A study of Mus musculus with 43 samples.

How the data were processed

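The deposited files hold 43 Mouse Genome 430 2.0 arrays, each with the signals of 45101 probe sets, of which 64 are control probe sets. Per the submitters' processing notes, the signals were computed in GCOS 1.3. The unit of the deposited values is signal intensity on a linear scale. The notes give no target, and the 2% trimmed mean of each array, computed here from the values, lay between 499.794 and 499.845, so the authors had scaled all arrays to 1 trimmed mean. Detection calls were not used. Per the labels, biotin-labelled cRNA was hybridised. The authors also deposited a table of probe sets changed over the time course, whose p values (the unit p_value) the authors had adjusted to a false discovery rate (FDR), per the file headers, and its cluster numbers were used as the authors gave them. That table was only set beside the results here and entered no test.

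Signals were changed to log2(signal + 16), and every log2 value in the text is on this scale, which was computed here from the deposited linear signals. A probe set was tested when its signal was above its array's median on at least 3 arrays, which left 32184 probe sets. Genes were assigned from the probe annotation supplied with the series: 34958 probe sets carried 1 gene name, 932 carried several and 9211 carried none. Among the tested probe sets 26336 carried 1 gene, for 14534 genes. Gene names were compared with the RefSeq gene table of the mouse assembly GRCm38.p6: 34754 were found by gene identifier and 0 were changed; no coordinates were used. The groups came from the sample labels alone: 1 starved group, 10 IL-2 times and 2 times without IL-2.

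Differences between groups were tested with limma 3.58.1 in R 4.3.3. One mean per group was fitted to all 43 arrays, which leaves 30 residual degrees of freedom, and variances were moderated with a mean-variance trend. All tests were two-sided. Benjamini-Hochberg adjustment ran over the 32184 probe sets in each of 15 comparisons, and a probe set was called at an adjusted p under 0.05. The comparisons were IL-2 against no IL-2 at 4 h and at 8 h, the difference between those 2 effects, no IL-2 at 4 h and at 8 h against starved 0 h, and each of the 10 IL-2 times against starved 0 h. An F test over the 10 IL-2 times and starved 0 h was added as an overall test. The median residual standard deviation was 0.552 on the log2 scale. Errors beside a log2 difference are limma's standard errors.

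Gene lists were written from general knowledge of T cells and of IL-2. They were IL-2 and STAT5 response, immediate early, ribosome biogenesis, aminoacyl tRNA synthetases, G1/S and DNA replication, G2/M and mitosis, quiescence and FoxO targets, pro-apoptotic, anti-apoptotic, glycolysis, cholesterol synthesis, proteasome, ATF4 and amino acid response, chaperones, interferon response, cytotoxic effectors and cytokines, purine, pyrimidine and one-carbon synthesis, p53 targets, oxidative phosphorylation, autophagy and lysosome, T cell identity, and markers of B cells, macrophages, fibroblasts and erythroid cells. Each of these 25 lists was tested against the other genes with camera at a preset correlation of 0.01, on 1 probe set per gene and 14479 genes, with adjustment over the 25 lists in each comparison. The test was repeated with a correlation estimated from the data, which is stricter. Some genes sit on more than 1 list: 7 of 29 on the IL-2 and STAT5 list, 7 of 30 on the cytotoxic list, 6 of 20 on the p53 list and 5 of 22 on the pro-apoptotic list.

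Named genes followed a rule. Each comparison of IL-2 with no IL-2 named the 10 called genes with the largest rise and the 10 with the largest fall. Each comparison of no IL-2 with starved 0 h named 5 and 5, and each IL-2 time and the difference of effects named 3 and 3. Except for the difference of effects, a gene was eligible when all arrays of one group lay above all arrays of the other. Each gene was represented by its probe set with the highest mean. A fixed panel of 20 genes known from IL-2 signalling, of which 19 were measured, and the 3 called members with the largest change in each list were named as well. The comparisons, lists, rule and first set of alternatives were chosen before the data were examined.

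That first set held pseudocounts of 1 and of 64, quantile normalisation, median centring, no filter, a filter at the 75th percentile, a fit to only the arrays compared, replicate number as a block, array weights, no variance trend, scan day as a fixed or a random block, a 2-fold minimum, an adjusted p under 0.01, each array left out in turn, the estimated correlation, and the mean of a gene's probe sets. Alternatives added after the data were seen left out the 7 arrays of scan day 2, kept only the arrays of scan day 3, or ranked genes for the list test by the fit with a random scan-day block. Scan days 1 to 8, in scan years 1 and 2, were read from the experiment files that came with the arrays.

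The tests were tested on simulated data, in which 50 probe sets per fold were changed in data drawn with the spread of these arrays. At 4-fold, 64% were recovered for IL-2 against no IL-2 at 4 h, 78% at 8 h, 34% for the difference of effects and 68% for IL-2 at 1 h; at 1.5-fold these were 10%, 2%, 4% and 8%. A list of 25 genes raised 1.5-fold at 8 h had an adjusted p of 2.28e-07 by camera, and 0 of the 24 unchanged lists were called. The simulated genes were drawn independently of each other, so this cannot tell how often lists of correlated genes are called falsely. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.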

Results

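Gene expression was measured on 43 arrays in CTLL-2, a mouse cytotoxic T cell line that needs interleukin 2 (IL-2), a T cell growth factor, to survive and divide. The cells were first kept without IL-2 for 14 h, and 5 arrays measured them at that point (starved 0 h). Human recombinant IL-2 at 100 U/mL was then added, and arrays were made at 0.5, 1, 2, 6, 8, 10, 12, 16 and 24 h with n = 3 each and at 4 h with n = 4. Other cells stayed without IL-2 for a further 4 h (n = 4) or 8 h (n = 3). The number of arrays limits the precision of every value. The series design calls the replicates of the IL-2 times biological and does not describe those of the cells kept longer without IL-2. The p-values rest, for each probe set, on 1 spread within groups pooled over all 43 arrays, not on that of the groups compared alone. The 2% trimmed mean signal was about the same on every array, from 499.794 to 499.845, whereas the median signal ran from 46.1 to 118.6. Where the lower of 2 group means lies near or below those medians, the size of a log2 difference depends on the pseudocount and is not exact. That holds for the differences given below for Fos, Enah, Fbxo32, Il23a, Cdc6, Mxd4, Pik3ip1, Klhl24, Maff, Osbpl5, Cysltr1, Ifng, Spin4, Cdc7, Rnf207 and Sema3a. The 7 arrays of scan day 2 lay at 96.3 to 118.6 and the other 36 at 46.1 to 76.5. All 7 arrays kept without IL-2 beyond 0 h were scanned in scan year 2 and the other 36 in scan year 1, so none of these 7 shares a scan day with an array of IL-2 or of starved 0 h. The 3'/5' signal ratio of actin, a measure of RNA quality, was 1.18 to 1.53 in scan year 2 (median 1.34) and 1.07 to 1.36 in scan year 1 (median 1.16). The array labelled no IL-2 4 h replicate 2 read closer to the IL-2 arrays than to the other 3 of its group. On probe sets at least 4-fold higher in IL-2 8 h than in no IL-2 8 h it lay at 0.725 of the way from those 3 arrays to the IL-2 4 h arrays.

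The time course asks which genes change after IL-2 is added and in what order. Every IL-2 time was set against starved 0 h, so IL-2 and further time in culture cannot be told apart in it. Cells kept without IL-2 for a further 4 h, scanned in another scan year, also differed from starved 0 h. There 2579 probe sets were called, and the ribosome biogenesis list had a median of 0.85. Without the array labelled no IL-2 4 h replicate 2 these values were 1325 and 0.43. At 0.5 h the changes were few and large. Fos, an immediate early transcription factor, rose over starved 0 h (log2 difference 5.59 ± 0.68 SE, n = 3 and 5), from a mean signal of 51.6 ± 50.0 SD to 2567 ± 516. The starved mean lies below the median signals of those arrays (65.4 to 112.2), so the size of this rise depends on the pseudocount (6.35 with 1 and 4.59 with 64). Egr1, of the same class, rose by 4.38 ± 0.57, and Socs3, a feedback inhibitor of cytokine signalling, by 5.03 ± 0.49. Of the 25 measured genes of the immediate early list 9 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 6.28e-43, and adjusted p = 5.09e-07 with an estimated correlation). On the IL-2 and STAT5 response list 6 of 28 rose (camera adjusted p = 3.96e-12, adjusted p = 0.0636 with an estimated correlation), with Socs1 at 3.00 and Cish at 2.40, both feedback inhibitors. Their calls ended without IL-2 0.5 h replicate 3, with values of 2.81 and 2.38. The fibroblast markers were called by the preset test at a median of 0.57 with 0 members passing alone (adjusted p = 0.036, and adjusted p = 0.495 with an estimated correlation). That call ended without starved 0 h replicate 4 (0.31) or 5 (0.59) or IL-2 0.5 h replicate 1 (0.60) or 2 (0.34), and the median was 0.93 without replicate 3. The preset test called 8 lists at 0.5 h, and 6 of these calls ended in at least 1 fit without 1 array. Besides those above they were ribosome biogenesis, aminoacyl tRNA synthetases, G1/S, G2/M and interferon response. In all, limma called 43 probe sets at 0.5 h, 36 of them higher (83.7%, against 72.2% under median centring). The count was 28 without replicate 1, 28 without replicate 2 and 19 without replicate 3 of IL-2 0.5 h. Of these 3 arrays, 2 came from scan day 2, and all 43 probe sets had the same sign within scan days 2 and 3.

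At 1 and 2 h further genes rose. Hbegf, an EGF-family growth factor, rose by 5.12 ± 0.70 at 1 h (n = 3 and 5), and Enah, an actin regulator, by 4.29 ± 0.61. Myc, a transcription factor that drives cell growth, rose by 3.76 ± 0.56 at 1 h and 4.39 ± 0.56 at 2 h, and Cish reached its highest mean signal at 2 h, 13342 ± 1127 SD against 840 ± 299 at 0 h. Il2ra, the alpha chain of the IL-2 receptor, rose by 1.64 ± 0.31 at 2 h. The immediate early list still held 14 rises of 25 at 1 h and 8 at 2 h, with median differences of 1.14 and 0.62 (camera adjusted p = 3.65e-06 and adjusted p = 0.0177 with an estimated correlation). Falls came with Osbpl5, a lipid transfer protein, at −3.10 ± 0.61, and Fbxo32, a ubiquitin ligase subunit known as a target of the starvation-linked FoxO factors, at −3.01 ± 0.60, both at 2 h. The quiescence and FoxO target list had 1 rise and 6 falls of 26 at 2 h (median −0.60, camera adjusted p = 1.72e-04, adjusted p = 0.404 with an estimated correlation). The test called 167 probe sets at 1 h (125 higher) and 905 at 2 h (529 higher, 58.5%, against 71.7% under median centring). At 1 h the count was 84 without replicate 2 and 83 without replicate 3 of IL-2 1 h. At 2 h it was 469 without replicate 1 and 346 without replicate 3 of IL-2 2 h.

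From 4 to 12 h ribosome biogenesis, nucleotide synthesis and cell cycle lists changed. By the preset test the nucleotide synthesis list was first called at 4 h. The ribosome biogenesis, G1/S and G2/M lists were first called at 0.5 h. Those early calls ended in 3, 4 and 4 of the 8 fits without 1 array. Of 34 ribosome biogenesis genes, 30 rose at 4 h and 0 fell (31 and 0 adjusted over the list alone). Their median difference was 1.80 (n = 4 and 5, camera adjusted p = 6.16e-36, adjusted p = 0.0356 with an estimated correlation). Examples are Rrp9 at 3.88, Polr1b, a subunit of RNA polymerase I, at 2.94 and Nop56 at 2.72. The purine, pyrimidine and one-carbon synthesis list peaked at 12 h with 19 of 23 higher and 0 lower (median 1.77, n = 3 and 5, camera adjusted p = 1.75e-18, adjusted p = 0.0104 with an estimated correlation), with Gart at 2.98. The list also holds Srm, spermidine synthase (3.41), which makes a polyamine and not a nucleotide. Il23a, a subunit of the cytokine IL-23, rose by 5.83 ± 0.62 at 8 h, Hbegf by 5.92 ± 0.70 and Il2ra by 2.33 ± 0.31. The IL-2 and STAT5 list was called at all 10 times by the preset test, but with an estimated correlation it was not called at 0.5, 6, 16 and 24 h (adjusted p = 0.0636, 0.0588, 0.108 and 0.159). It had its most rises at 10 h, 21 of 28, with 1 fall, that of Ctla4 (−3.96). Its median then was 1.34 (camera adjusted p = 2.9e-14, adjusted p = 0.0327 with an estimated correlation). Proteasome genes rose at 12 h, 14 of 31 with 0 falls (median 0.48, camera adjusted p = 9.03e-09, adjusted p = 0.0771 with an estimated correlation). Cell cycle genes split in time. The G1/S and DNA replication list had 24 rises of 45 at 8 h, 38 at 10 h and 39 at 12 h, with 0 falls at each. The G2/M and mitosis list had 28 falls of 41 and 0 rises at 4 h (39 and 0 adjusted over the list alone, median −1.67, camera adjusted p = 1.67e-10, adjusted p = 0.377 with an estimated correlation).

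Genes known from quiescence and interferon signalling fell over the same hours. Mxd4, an antagonist of MYC, fell by 5.34 ± 0.69 on the log2 scale at 8 h (n = 3 and 5), and Pik3ip1, an inhibitor of PI3-kinase, fell by 5.23 ± 0.70 at 10 h. On the quiescence list 17 of 26 genes fell and 1 rose at 10 h (median −1.39, camera adjusted p = 8.72e-07, adjusted p = 0.0558 with an estimated correlation). Interferon response genes fell, 12 of 20 with 0 rises at 8 h (median −1.28, camera adjusted p = 3.47e-06, adjusted p = 0.0306 with an estimated correlation), led by the guanylate-binding proteins Gbp2 at −3.17 and Gbp3 at −2.52. Bcl6, a transcriptional repressor, lay at −1.97 ± 0.38 at 4 h. Cytotoxic effector and cytokine genes were called at 8 h, 4 higher and 3 lower of 25 (median 0.17, camera adjusted p = 0.0448, adjusted p = 0.42 with an estimated correlation). That call ended without starved 0 h replicate 2, 3 or 5 or IL-2 8 h replicate 2, with medians of 0.15, 0.08, 0.12 and −0.01. The pro-apoptotic list was not called at 10 h (median −0.49, adjusted p = 0.345), with 4 members higher and 8 lower, among them the BH3 factors Bmf at −2.98 and Bcl2l11 at −2.95. Oxidative phosphorylation genes were called at 8 h with 4 higher and 0 lower of 36 (median 0.15, camera adjusted p = 0.00302, adjusted p = 0.42 with an estimated correlation), and not without starved 0 h replicate 2 (0.07) or IL-2 8 h replicate 2 (0.06). Probe sets called numbered 4855 at 4 h, 5417 at 6 h, 6160 at 8 h, 6443 at 10 h and 6228 at 12 h, and 4075 at 12 h without IL-2 12 h replicate 1. The share of rises was 43.2%, 40.2%, 37.1%, 39.5% and 40.9% in that order, and 74.7%, 53.6%, 62.7%, 69.2% and 67.3% after median centring. Under the deposited scaling the median of all probe sets lay at −0.21, −0.03, −0.14, −0.23 and −0.20.

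By 16 and 24 h the cells expressed genes of DNA replication and mitosis. Cdc6, which loads the replicative helicase, rose by 4.95 ± 0.60 at 16 h (n = 3 and 5), from a mean signal of 69.2 ± 59.8 SD, close to background. Of the 45 G1/S and DNA replication genes 43 rose at 16 h and 0 fell (44 and 0 adjusted over the list alone, median 2.09, camera adjusted p = 6.01e-41, adjusted p = 0.0145 with an estimated correlation), with Pole at 3.42 and Gins1 at 3.27. Ccne1, cyclin E1, rose by 2.02 ± 0.35. The G2/M and mitosis list turned to 13 rises and 0 falls of 41 at 16 h, with Top2a at 2.71, Bub1 at 2.34 and Aurkb at 2.33 (median 1.21, adjusted p = 0.385 with an estimated correlation). At 24 h it had 17 rises and 0 falls (29 and 0 adjusted over the list alone, median 1.58, camera adjusted p = 3.92e-18, adjusted p = 0.159 with an estimated correlation). Chaperone genes rose, 17 of 21 at 16 h with 0 falls (median 0.95, camera adjusted p = 9.09e-16, adjusted p = 0.0181 with an estimated correlation), as did 8 of 19 aminoacyl tRNA synthetases (median 0.51, adjusted p = 0.0145 with an estimated correlation) and 9 of 21 genes of the ATF4 and amino acid response (median 0.83, adjusted p = 0.0611 with an estimated correlation). Autophagy and lysosome genes were called lower at 16 h, with 10 falls and 1 rise (median −0.49, camera adjusted p = 0.00229, adjusted p = 0.178 with an estimated correlation), and not without IL-2 16 h replicate 1 (−0.34), an array whose GAPDH 3'/5' ratio was 1.41 against 0.968 or less elsewhere. Cholesterol synthesis was called at 24 h with 3 rises (median 0.36, camera adjusted p = 0.00147, adjusted p = 0.398 with an estimated correlation), but not without IL-2 24 h replicate 2, when its median was 0.04. Without IL-2 24 h replicate 1 its median was 0.56.

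At 24 h several early genes were still above starved 0 h. Il2ra was higher by 1.50 ± 0.31 and Cish by 1.89 ± 0.45 (n = 3 and 5). Without IL-2 24 h replicate 1 the calls ended for Cish (1.18), Myc (1.65 against 2.50), Ccne1 (0.82 against 1.34) and Socs1 (1.78 against 2.04), and the last also without replicate 2 (1.54). The test called 4952 probe sets at 16 h (44.3% higher, 73.3% after median centring) and 2828 at 24 h (39.2%, 70.2%), with medians of all probe sets of −0.19 and −0.17. At 16 h the count was 2751 without IL-2 16 h replicate 1. The IL-2 24 h arrays had mean correlations of 0.887, 0.896 and 0.913 with their own group, the lowest of all arrays. The pooled spread does not show this, and the 24 h count was lower in a fit to only the arrays compared, as given below. Within the scan days that hold both groups, 98.4% to 100% of the called probe sets of each IL-2 time had the same sign as in all arrays; those arrays are part of the same fit, so this is not an independent test. Of the called list results 38 of 46 kept their sign on scan day 2 and 100 of 105 on scan day 3. On scan day 2 the G2/M median was 0.63 at 0.5 h, 0.89 at 2 h and 0.12 at 6 h, against −1.42, −1.91 and −2.24 on scan day 3. Kept to scan day 3 the 24 h comparison called 3 probe sets, with 1 array of IL-2 24 h left. The glycolysis, p53, pro-apoptotic, anti-apoptotic, T cell identity, B cell, macrophage and erythroid lists were called at none of the 10 times by limma's camera test.

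**Figure D1:**
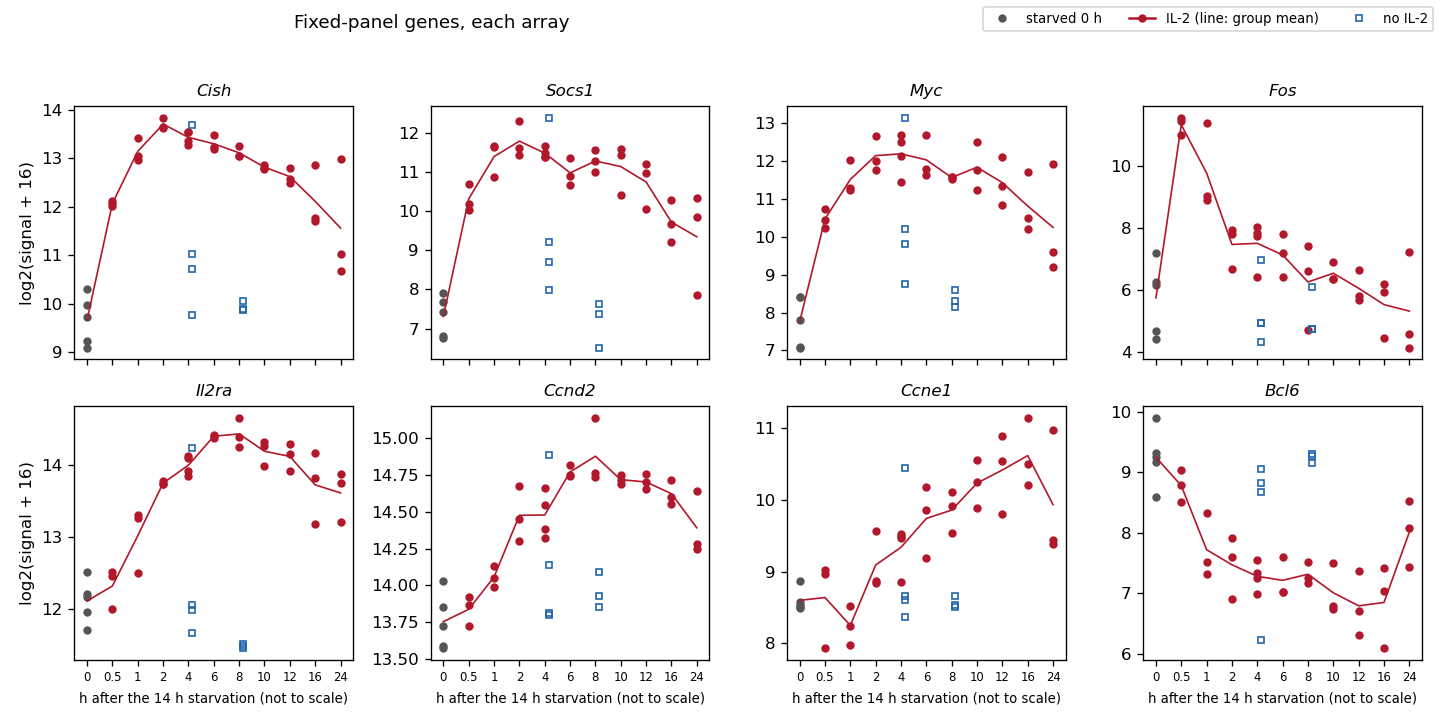
Log2(signal + 16) of 8 genes on each array (y) against hours after the 14 h starvation (x, not to scale), with starved 0 h in grey, IL-2 in red (line through the group means) and no IL-2 as blue open squares. Fos peaks at 0.5 h and Cish at 2 h, and 1 of the 4 no IL-2 4 h squares lies near the IL-2 arrays for Il2ra and Bcl6.

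Over the whole time course the F test called 8620 probe sets, 11566 having an unadjusted p under 0.05. The authors' deposited table lists 3838 probe sets in 9 clusters, and 3544 of them (92.3%) were among the 8620, with 294 not called; 1028 would be shared if the lists were independent. That table was drawn from these same samples, so the overlap is no independent evidence. By this fit the authors' cluster 8, of 159 probe sets, had a median difference of −1.15 at 4 h and 0.78 at 24 h, and cluster 9, of 335, had 1.11 at 4 h and 0.10 at 24 h. Cluster 7, of 662, was lower throughout these times, at −1.03 at 4 h, −1.30 at 10 h and −0.78 at 24 h.

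The comparison of IL-2 with no IL-2 at 4 h holds time in culture equal, but its 2 groups were scanned in different scan years. The response to IL-2 and scan year therefore cannot be told apart in it. With IL-2, Ifng, the cytokine interferon gamma, was higher by 3.48 ± 0.62 (n = 4 and 4, against a mean signal of 41.2 without IL-2, so not an exact size), Hbegf by 3.55 ± 0.68 and Irf4, a transcription factor of activated T cells, by 3.26 ± 0.58. Hbegf lay at a log2 signal of 12.27 in the array labelled no IL-2 4 h replicate 2 and at 6.69 to 9.19 in the other 3 of that group, and its difference without that array was 4.59. Cish was higher by 2.13 ± 0.43, Socs3 by 2.75 ± 0.48, Il2ra by 1.51 ± 0.30 and Bcl2, which blocks apoptosis, by 1.35 ± 0.34. Cysltr1, a leukotriene receptor, had the largest difference, 5.69 ± 1.00 against a mean signal of 10.9 without IL-2, which is too low to give an exact size, and Csn2, a casein, differed by 3.15 ± 0.27. Both also separated all arrays of scan year 2 from all of scan year 1. Lower with IL-2 were Osbpl5 at −3.56 ± 0.59, Tspan32 at −3.10 ± 0.42, Trp53inp1, a stress protein, at −2.89 ± 0.49 and the cytokine Il16 at −2.71 ± 0.54. On the IL-2 and STAT5 list 15 of 28 genes rose and 1 fell (17 and 3 adjusted over the list alone, median 1.04, camera adjusted p = 8.71e-08, adjusted p = 0.406 with an estimated correlation). Ribosome biogenesis had 16 rises and 1 fall of 34 (21 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 1.96e-10, adjusted p = 0.527 with an estimated correlation), with Rrp12 at 1.84 and Gnl3 at 1.68. The G2/M list had 21 falls and 0 rises of 41 (median −1.68, camera adjusted p = 1.86e-10, adjusted p = 0.527 with an estimated correlation), with Kif23 at −2.50 and Ube2c at −2.48. Immediate early genes (median 0.45), ATF4 and amino acid response genes (−0.65), quiescence genes (−0.79) and oxidative phosphorylation genes (−0.26) were called as well, with 9, 7, 10 and 7 members passing in that direction and adjusted p = 0.406, 0.527, 0.527 and 0.527 with an estimated correlation. The immediate early median was 0.74 without the array labelled no IL-2 4 h replicate 2.

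In the same comparison 4 further lists were called with all arrays and lost their call without at least 1 of them. The G1/S list had 13 falls and 2 rises of 45 (median −0.66, camera adjusted p = 9.88e-04, adjusted p = 0.695 with an estimated correlation) and was not called without the array labelled no IL-2 4 h replicate 2 (−0.61, adjusted p = 0.084). Aminoacyl tRNA synthetases had 7 falls and 1 rise of 19 (median −0.47, adjusted p = 0.527 with an estimated correlation) and were not called without IL-2 4 h replicate 1 (−0.49). Cytotoxic effectors had 7 falls and 2 rises of 25, the rises being Ifng and Lta (1.51), with a median of −0.53 (adjusted p = 0.527 with an estimated correlation), and were not called without IL-2 4 h replicate 3 (−0.48) or 4 (−0.45), no IL-2 4 h replicate 4 (−0.40) or the array labelled no IL-2 4 h replicate 2 (−0.45). Chaperones had 3 rises and 1 fall, of Hspa1b by −1.40 (median 0.26, adjusted p = 0.693 with an estimated correlation), and were not called without IL-2 4 h replicate 1 (0.22) or 2 (0.21) or no IL-2 4 h replicate 1 (0.19), 3 (0.09) or 4 (0.24). Without the array labelled no IL-2 4 h replicate 2 chaperones were at 0.43 (adjusted p = 5.15e-04). The 14 lists not called included glycolysis (median −0.01, mean 0.18, adjusted p = 0.561), where Hk2 and Slc2a1 were higher with IL-2 by 2.55 and 2.30. Slc2a1 lay at −3.34 in no IL-2 4 h against starved 0 h, so its difference here is no rise over the starved level. Also not called was the pro-apoptotic list (median −0.17, adjusted p = 0.601), where Bbc3, Bmf and Casp9 were lower by 2.11, 2.01 and 1.69 on the log2 scale. The 14 lists also held the anti-apoptotic list (median 0.08, mean −0.01, adjusted p = 0.63), cholesterol synthesis (−0.05, 0.99), the proteasome (0.06, 0.188), interferon response (−0.36, 0.109), purine synthesis (0.32, 0.205), p53 targets (−0.17, 0.0935), autophagy (−0.19, 0.197) and T cell identity (−0.13, 0.438). Markers of B cells (−0.54, 0.543), macrophages (−0.01, 0.99), fibroblasts (0.00, 0.556) and erythroid cells (0.16, 0.63) had 0 members passing. The test called 4664 probe sets, 2344 higher and 2320 lower with IL-2, for 1456 and 1739 genes. The count was 2997 without no IL-2 4 h replicate 3 and 2711 without no IL-2 4 h replicate 4. Without the array labelled no IL-2 4 h replicate 2 it was 5887. The genes Bcl6 (−1.57), Ccnd2 (0.56), Egr1 (2.03) and Ccng2 (−2.43) then gained a call and Gzmb (−0.45) lost it. Of the lists, interferon response (−0.50, adjusted p = 0.0338), purine synthesis (0.53, adjusted p = 0.0132) and the proteasome (0.17, adjusted p = 0.0402) gained a call without that array. With scan day as a random block it was 2031.

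The comparison at 8 h asks the same of a later time. Il23a was higher with IL-2 by 6.98 ± 0.70 (n = 3 and 3), at mean signals of 6975 and 45.0. The lower of these is under the median signals of its arrays (61.0 to 69.5), so the size depends on the pseudocount. Hbegf was higher by 6.16 ± 0.78, Maff by 4.65 ± 0.59, the kinase gene Pim3 by 4.51 ± 0.62 and Socs1 by 4.11 ± 0.60. Il2ra was higher by 2.95 ± 0.34, Cish by 3.17 ± 0.50, Myc by 3.22 ± 0.63, Bcl2 by 2.28 ± 0.39 and Ccnd2, cyclin D2, by 0.92 ± 0.19. Lower were Mxd4 at −5.17 ± 0.77, Pik3ip1 at −4.83 ± 0.79, Klhl24 at −4.30 ± 0.62, Trp53inp1 at −3.95 ± 0.56 and Bcl6 at −1.93 ± 0.46. Of the 28 IL-2 and STAT5 genes 20 rose and 0 fell (21 and 1 adjusted over the list alone, median 1.97, camera adjusted p = 1.69e-13, adjusted p = 0.0747 with an estimated correlation). Ribosome biogenesis had 17 rises and 1 fall of 34 (median 1.10, adjusted p = 0.369 with an estimated correlation), with Rrp9 at 3.11. The G1/S list had 17 rises and 0 falls of 45 (median 0.66, adjusted p = 0.533 with an estimated correlation), with Cdc6 at 3.18 and Orc1 at 3.02. The G2/M list had 7 falls and 1 rise of 41 (median −1.29, adjusted p = 0.77 with an estimated correlation), with Ccnb2 at −3.33. Glycolysis had 6 rises and 0 falls of 18 (median 0.57, adjusted p = 0.369 with an estimated correlation), led by the glucose transporter gene Slc2a1 at 3.66 and hexokinase 2, Hk2, at 3.35. The glycolysis median was 0.38 without IL-2 8 h replicate 3 and 0.37 without no IL-2 8 h replicate 1. Interferon response genes had 8 falls and 0 rises of 20 (median −0.77, camera adjusted p = 7.21e-04, adjusted p = 0.249 with an estimated correlation), with Gbp2 at −3.66. Quiescence genes (13 falls, 2 rises, median −1.35) and purine synthesis genes (9 rises, 1 fall, median 0.74) were called with adjusted p = 0.369 each with an estimated correlation.

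Smaller shifts at 8 h were called for the immediate early (median 0.20), proteasome (0.27), chaperone (0.39) and cholesterol lists (0.47), with 8, 7, 6 and 7 rises and adjusted p = 0.369, 0.483, 0.483 and 0.699 with an estimated correlation. The cholesterol call ended without IL-2 8 h replicate 2 (0.38, adjusted p = 0.0594), and the median was 0.30 without no IL-2 8 h replicate 2. The pro-apoptotic list was not called (median −0.42, adjusted p = 0.701), with falls of Pdcd4 (−3.67), Bmf (−3.21) and Bcl2l11 (−2.90) and 4 rises, nor was the anti-apoptotic list (median −0.06, mean 0.10, adjusted p = 0.689), with rises of Bcl2l1 (1.88) and Cflar (1.70). Cytotoxic effectors were not called either, their median being −0.43 and their mean 0.10 (adjusted p = 0.582). limma called 6358 probe sets, 2799 higher and 3559 lower with IL-2, for 1892 and 2478 genes, and 4298 with scan day as a random block. Without 1 array at a time the count ran from 4756 to 5435, all below the full count. All 3 no IL-2 8 h arrays had an actin 3'/5' ratio of 1.41 to 1.53, above the 1.11 to 1.18 of the IL-2 8 h arrays, and condition and scan year cannot be told apart at either time.

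The effect of IL-2 at 8 h was tested against its effect at 4 h. The largest differences were in Cdc7, a replication kinase, at 3.02 ± 0.48 (n = 3, 3, 4 and 4), Rrm2, a subunit of ribonucleotide reductase, at 2.33 ± 0.47 and the costimulatory receptor gene Tnfrsf9 at 2.08 ± 0.38, and in Pink1, a mitochondrial kinase, at −2.29 ± 0.47, Grina at −1.64 ± 0.31 and Hspa4l at −1.56 ± 0.33. The G1/S list differed by a median of 1.19 (24 genes adjusted over the list alone, camera adjusted p = 1.61e-26) and the IL-2 and STAT5 list by 0.73, or 0.30 without the array labelled no IL-2 4 h replicate 2. The lowest adjusted p of any list was 0.112 with an estimated correlation. In all, 16 probe sets were called, 10 with a higher and 6 with a lower value at 8 h, while 3110 had an unadjusted p under 0.05. Under quantile normalisation 5 were called and under median centring 2, all of them higher. Single arrays decided this count. It was 63 without no IL-2 4 h replicate 1, 7 without replicate 3 and 2 without the array labelled no IL-2 4 h replicate 2. It was 2, 4, 25 and 25 without IL-2 4 h replicates 1, 2, 3 and 4, 4, 3 and 1 without IL-2 8 h replicates 1, 2 and 3, and 0, 2 and 4 without no IL-2 8 h replicates 1, 2 and 3. Of the 14 fits without 1 array, Pink1 lost its call in 11, Hspa4l in 11, Rrm2 in 10, Grina in 7, Tnfrsf9 in 6 and Cdc7 in 1. Cdc7 was at 2.82 (adjusted p = 0.0804) without no IL-2 8 h replicate 1. Without the array labelled no IL-2 4 h replicate 2, Rrm2 was at 2.35 (adjusted p = 0.136), Tnfrsf9 at 1.90 (0.0801), Pink1 at −1.87 (0.14), Grina at −1.33 (0.0671) and Hspa4l at −1.36 (0.155).

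Cells kept without IL-2 were compared with starved 0 h to see what further starvation changed. Slc2a1, the glucose transporter, fell at 4 h (−3.34 ± 0.43, n = 4 and 5) and at 8 h (−3.74 ± 0.47, n = 3 and 5). Its mean signal was 11417 ± 1958 SD at starved 0 h and 834 ± 63.8 after 8 h more without IL-2. Spin4 lay at −3.88 ± 0.59 and −4.21 ± 0.64, but its mean signal without IL-2 (7.88 and 2.60) is too low to give an exact size, and it separated the scan years as well. Clec2d was higher by 2.65 ± 0.45 and 2.60 ± 0.49, and it too separated the scan years. Glycolysis genes had 3 falls at 4 h and 6 at 8 h of 18, with 0 rises (6 and 7 falls adjusted over the list alone, medians −0.46 and −0.50, adjusted p = 0.253 and adjusted p = 0.152 with an estimated correlation), with Hk2 at −2.22 and Aldoc at −1.70 at 8 h. The 4 h call ended without starved 0 h replicate 4 (−0.38, adjusted p = 0.0588). Ribosome biogenesis genes had 13 rises of 34 at 4 h and 4 at 8 h, with 0 falls (medians 0.85 and 0.45, adjusted p = 0.17 and adjusted p = 0.483 with an estimated correlation), with Dkc1 at 2.30 at 4 h. Without the array labelled no IL-2 4 h replicate 2, which reads like IL-2, the 4 h median was 0.43. Oxidative phosphorylation genes had 5 and 8 rises of 36 (9 and 16 adjusted over the list alone, medians 0.27 and 0.33, adjusted p = 0.17 and adjusted p = 0.152 with an estimated correlation), with Cycs, cytochrome c, at 1.23 at 8 h. Cytotoxic effectors had 3 and 7 rises of 25 and 0 falls (medians 0.38 and 0.48, adjusted p = 0.17 and adjusted p = 0.152 with an estimated correlation). At 4 h purine synthesis had 7 rises of 23 (median 0.66, adjusted p = 0.115 with an estimated correlation), and a median of 0.31 without that array. The ATF4 list had 3 and 5 rises (medians 0.27 and 0.49, adjusted p = 0.228 and adjusted p = 0.152 with an estimated correlation).

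Of the panel genes Myc (2.73), Pim1 (1.39), Socs1 (2.26) and Cish (1.63) were called higher at 4 h without IL-2, and 0 of the 19 measured genes at 8 h. Without the array labelled no IL-2 4 h replicate 2, Myc was at 1.84, Socs1 at 1.32, Pim1 at 0.91 and Cish at 0.84 (adjusted p = 0.12, the call of Cish alone being lost). The calls on the quiescence list (median 0.06 against −0.33), the G1/S list (0.09 against 0.29) and the proteasome (0.05 against 0.15) ended as well. With an estimated correlation none of the 3 was called (adjusted p = 0.394, 0.65 and 0.413). The G1/S call also ended without starved 0 h replicates 1, 2 and 5 (0.25, 0.20 and 0.09) and the proteasome call without starved 0 h replicate 2 (0.03). At 4 h limma called 2579 probe sets, 832 higher and 1747 lower, and at 8 h 1757, 728 higher and 1029 lower. The share of rises was 32.3% and 41.4%, and 76.7% and 75.1% after median centring, the median of all probe sets lying at −0.18 and −0.11 before it. The 4 h count was 1687 without starved 0 h replicate 3, 1603 without no IL-2 4 h replicate 4 and 1325 without the array labelled no IL-2 4 h replicate 2. The 8 h count was 590, 978 and 780 without no IL-2 8 h replicates 1, 2 and 3. With scan day as a random block the counts were 469 and 390. Scan year and further starvation cannot be told apart here, since every starved 0 h array was scanned in year 1 and 0 of the 7 others were.

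**Figure D2:**
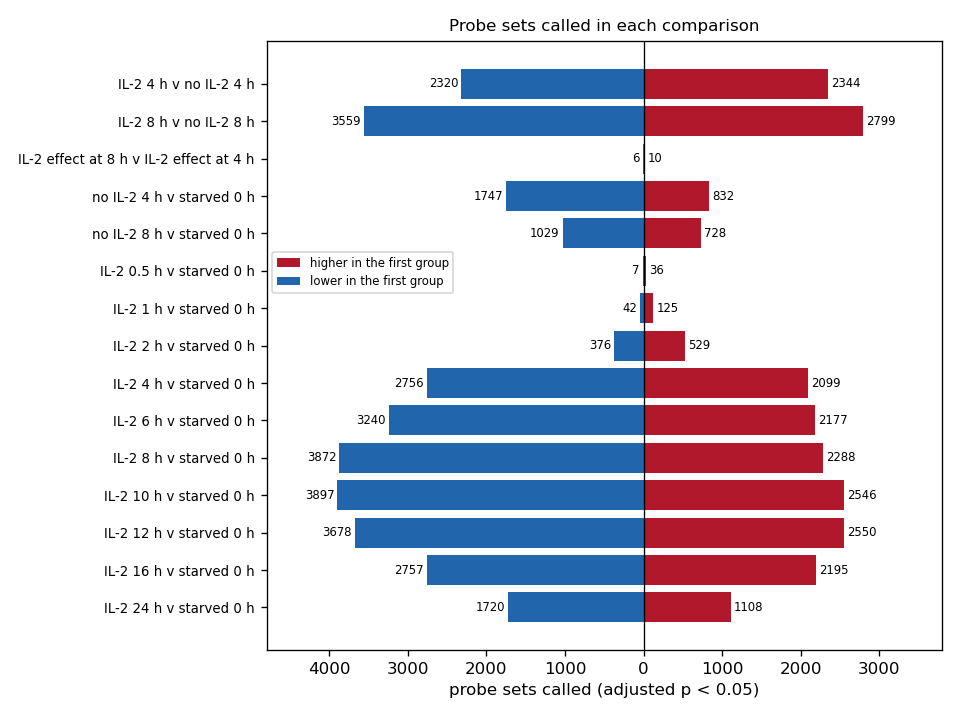
Number of probe sets called at an adjusted p under 0.05 (x) in each of the 15 comparisons (y), with bars to the right in red for probe sets higher and to the left in blue for probe sets lower in the first group named. Calls grow from 36 higher and 7 lower at 0.5 h of IL-2 to 2546 and 3897 at 10 h, and the difference between the 2 IL-2 effects has 10 and 6.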

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

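The tests weighed below of the array labelled no IL-2 4 h replicate 2, of the arrays without IL-2 against starved 0 h and of IL-2 24 h replicate 1 were chosen after the results were seen; the splits of the samples and the tests of the difference between 4 h and 8 h were chosen before.

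In groups of 4 or 5 arrays, 201 sets of values of named genes, lists and quality measures were searched for an array far from the rest of its group, and 22 were found, where chance gives about 10.05. Of these, 13 lay in the no IL-2 4 h group. The array labelled no IL-2 4 h replicate 2 stood apart for Il2ra (log2 signal 14.247), Pim1 (12.992), Ccne1 (10.441), Trp53inp1 (10.182), Lax1 (9.802), Tspan32 (9.168), Il16 (8.931), Arhgef18 (8.54), Ccng2 (8.137) and Bcl6 (6.225), and for the means of the quiescence and FoxO targets (8.959), proteasome (12.614) and ATF4 and amino acid response lists (10.498). Other arrays stood apart for Jag1 (4.154) and Socs2 (11.627) in starved 0 h replicate 4, Pim1 (9.555) in starved 0 h replicate 5, Ccne1 (8.876) and the median signal (112.2) in starved 0 h replicate 2 and the ribosome biogenesis list (10.045) in starved 0 h replicate 1. In IL-2 4 h, replicate 4 stood apart for Egr1 (11.344) and Ccne1 (8.863), and replicate 3 for the G2/M and mitosis list (8.984).

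The array labelled no IL-2 4 h replicate 2 read like the IL-2 arrays. A swap with an array labelled IL-2 4 h would leave a partner out of place, but all 4 of those arrays lay at positions of 0.838 or more between the other no IL-2 4 h arrays (0) and the IL-2 4 h arrays (1). Scan day 7 cannot be judged this way. The highest position of the other arrays without IL-2 scanned that day was 0.0689. Those arrays helped to set position 0 or to choose the probe sets, so low positions were fixed in advance. IL-2 in this culture or a wrong label may account for it, as the array lay at 0.725 on risen and 0.831 on fallen probe sets. RNA of IL-2-treated cells mixed with at least as much starved RNA would leave probe sets that fall with IL-2 at 0.5 or more of the signal of the other 3 arrays. Their median ratio was 0.342 (bootstrap range over probe sets 0.314 to 0.372). That range treats the probe sets as independent and holds no spread between arrays. The median argues against such a mixture for most of these probe sets. The test itself required an upper quartile under 0.5 and stays undecided, as that quartile was 0.525. A mixture with a smaller share of starved RNA stays open. Without this array, IL-2 against no IL-2 at 4 h called 5887 probe sets in place of 4664.

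The arrays without IL-2 differed from starved 0 h, and scan year may account for part of it. On 1192 probe sets called for no IL-2 8 h and not for IL-2 at 4 or 8 h, the array labelled no IL-2 4 h replicate 2, which otherwise reads like IL-2, lay at 0.670 between starved 0 h (0) and no IL-2 8 h (1). The other no IL-2 4 h arrays lay at 0.673 to 0.848 and the IL-2 4 h arrays at −0.0863 to 0.166. The choice of these probe sets itself puts the IL-2 4 h arrays near 0 and no IL-2 8 h near 1, so only the position of the array labelled no IL-2 4 h replicate 2 is informative. If it held some RNA of cells kept without IL-2, that position would not favour scan year either. In addition, 210 probe sets separated all 7 arrays of scan year 2 from all 36 of scan year 1, which is also the split by condition and so cannot favour scan year. Whether the scaling of each array to one trimmed mean gave the excess of falls over rises stays open, since the share of rises was at least 75.1% in both comparisons after median centring, which shifts all probe sets of an array alike, and 44.4% and 42.7% under quantile normalisation. Further starvation stays open beside scan year, as 0 arrays kept without IL-2 were scanned in scan year 1 and the 2 cannot be told apart.

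IL-2 24 h replicate 1 differed from replicates 2 and 3. Between no IL-2 8 h (0) and IL-2 8 h (1) it lay at 0.807 on risen and 0.796 on fallen probe sets, replicate 2 at 0.521 and 0.583 and replicate 3 at 0.530 and 0.449. Replicate 1 was scanned on scan day 2. A shift toward IL-2 8 h shared by the arrays of that day is argued against. In the other groups they differed from the rest of their group by −0.201 to 0.0215 on risen probe sets, against a gap of 0.282. Whether the cultures of that day answered more slowly was not tested. Replicate 1 correlated best with IL-2 6 h replicate 2, also of scan day 2. The state of an earlier time point, by a wrong label or a slower culture, may account for the difference of replicate 1. For it, 4 of 4 measures lay within the range of the 12 h and 16 h arrays, and no test separated a wrong label from a slower culture.

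With all arrays in, the effect of IL-2 differed between 8 h and 4 h, by a test of the difference itself, for Cdc7 (3.02), Rrm2 (2.33), Tnfrsf9 (2.08), Pink1 (−2.29), Grina (−1.64) and Hspa4l (−1.56), calls lost in 1, 10, 6, 11, 7 and 11 of the 14 fits without 1 array. Lists that differed, by their median, were IL-2 and STAT5 response (0.73, adjusted p = 2.53e-07), ribosome biogenesis (0.28, 0.0463), aminoacyl tRNA synthetases (0.40, 6.89e-04), G1/S and DNA replication (1.19, 1.61e-26), G2/M and mitosis (0.43, 0.0065), quiescence and FoxO targets (−0.47, 0.0463), glycolysis (0.80, 1.14e-04), cholesterol synthesis (0.68, 1.83e-04), proteasome (0.26, 0.00137), ATF4 and amino acid response (0.60, 3.92e-07), chaperones (0.27, 0.0174), interferon response (−0.45, 9.21e-04), purine, pyrimidine and one-carbon synthesis (0.39, 8.95e-05) and B cell markers (0.85, 0.0363). The lowest adjusted p among them was 0.112 with an estimated correlation. Leaving out 1 array ended 5 of these 14 calls. Without the array labelled no IL-2 4 h replicate 2 the medians were −0.14 for ribosome biogenesis, −0.18 for quiescence and 0.04 for chaperones, and lists that stayed called were at 0.30 for IL-2 and STAT5 response, 0.17 for the proteasome and −0.30 for interferon response. Ribosome biogenesis was also lost without IL-2 4 h replicates 3 (0.26) and 4 (0.19), IL-2 8 h replicates 1 (0.27) and 2 (0.15) and no IL-2 8 h replicates 1 (0.34) and 3 (0.23), and quiescence without IL-2 4 h replicates 2 (−0.47) and 4 (−0.40), IL-2 8 h replicate 2 (−0.27) and no IL-2 8 h replicates 1 (−0.47) and 2 (−0.47). Chaperones were lost without IL-2 4 h replicate 4 (0.21) and IL-2 8 h replicate 2 (0.19), G2/M without IL-2 4 h replicates 1 (0.19) and 4 (0.24) and IL-2 8 h replicate 2 (0.03), and B cell markers without IL-2 8 h replicate 3 (0.71), no IL-2 4 h replicate 4 (0.83) and no IL-2 8 h replicates 1 (0.80) and 2 (0.93). Medians that moved by over 1.5 times and stayed called were those of G2/M without IL-2 4 h replicates 2 (0.28) and 3 (0.84), IL-2 8 h replicate 3 (0.65) and no IL-2 4 h replicate 1 (0.25), of the proteasome without IL-2 8 h replicate 2 (0.16), of chaperones without IL-2 4 h replicate 3 (0.15), and of interferon response without IL-2 4 h replicates 1 (−0.28), 3 (−0.26) and 4 (−0.68).

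Other splits of the same arrays into groups of the same sizes were fitted. The splits argue against chance for IL-2 against no IL-2 at 4 h, where 1 of 35 splits, the real one, called as many as 4664 probe sets. That is the lowest share these splits can give. The highest other split called 2316, with the array labelled no IL-2 4 h replicate 2 among IL-2 4 h replicates 2, 3 and 4. At 8 h the 10 splits are too few (6358, highest other 0). For the difference of effects 1 of 100 splits, the real one, called as many as 16 (highest other 5). The other splits mixed 4 h with 8 h arrays, which widens the spread within groups and lowers their counts, so they cannot exclude chance. Chance is argued against for no IL-2 against starved 0 h at 4 h (1 of 100, with 2579 and highest other 883). The same holds at 8 h (1 of 56, with 1757 and highest other 155). The real splits of no IL-2 against IL-2 or starved 0 h are also splits by scan year, which these counts cannot tell from condition. For IL-2 at 0.5 h 2 of 56 splits called as many as 43. The highest other called 81, and it put starved 0 h replicate 2 with the 2 arrays of IL-2 0.5 h that were scanned on the same day, scan day 2. Kept to scan day 3, 22 probe sets were called at 0.5 h, but that day holds 1 array of IL-2 0.5 h, which the fit assumes to vary like the other groups. The share of 2 in 56 is under 0.05, but a split along scan day gives more calls than the real split does at this time. The splits therefore do not exclude chance at 0.5 h. At the 9 later times the real split alone called as many in 56 splits (100 at 4 h), which argues against chance but does not exclude it. The splits were not kept within scan days, where arrays had a correlation of 0.349, and were not adjusted for the number of tests. At 10 h and at 12 h, 2 of the arrays came from scan day 6, which holds no starved 0 h array. The real and highest other counts were 167 and 32 at 1 h, 905 and 88 at 2 h, 4855 and 2928 at 4 h, 5417 and 1725 at 6 h, 6160 and 1171 at 8 h, 6443 and 1038 at 10 h, 6228 and 869 at 12 h, 4952 and 834 at 16 h and 2828 and 1678 at 24 h. The 24 h split of 1678 put IL-2 24 h replicate 1 with the starved arrays and starved 0 h replicate 4 with IL-2 24 h. For the F test chance is argued against as well (1 of 100, with 8620 and highest other 324).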

How the results depend on the processing

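Leaving out the 7 arrays of scan day 2, keeping scan day 3 alone and ranking lists by the fit with a random scan-day block were chosen after the data were seen; the other alternatives were chosen before. Of 401 gene results, 397 kept their direction and side of the threshold with a pseudocount of 1, 390 with 64, 374 under quantile normalisation, 368 under median centring, 386 with a replicate block, 358 with array weights, 356 with a random scan-day block and 360 with the mean of a gene's probe sets. Fewer held with a fixed scan-day block (222 of 268 genes and 232 of 275 lists) and on scan day 3 alone (179 of 243 and 200 of 250). Of 375 list results the first 8 settings kept 365, 370, 317, 346, 339, 325, 343 and 345. The list calls depend on the preset correlation: 136 of 166 were lost with an estimated correlation. Signals near background limit small differences. The self-test, which did not vary background, recovered 2% to 10% of 1.5-fold changes in the 2 comparisons with and without IL-2. It made 100 and 94 calls there, against 4664 and 6358 in the data. Its adjusted threshold was therefore stricter, and recovery in the data may differ. Replicate numbers were not used to pair samples, and whether they carry a shared source stays open. Residuals of arrays sharing a number had a mean correlation of 0.0497, against −0.0191 for different numbers, and 24 of 43 arrays correlated best with one of their own number. Arrays sharing a scan day had 0.0749, and residuals of IL-2 and no IL-2 arrays at 4 h with the same number lay between −0.0201 and 0.0418. Except where fewer arrays or a stricter threshold gave a lower count, the cause was not tested.

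Counts moved beyond 1.5 times as follows. With array weights they were 9316 for IL-2 against no IL-2 at 4 h, 12039 at 8 h, 901 for the difference of effects, 4031 and 4862 for no IL-2 at 4 h and 8 h against starved 0 h, 124, 2734, 1633 and 9340 at 0.5, 1, 2 and 8 h of IL-2, and 16371 for the F test. With a random scan-day block they were 2031 for IL-2 against no IL-2 at 4 h, 79 for the difference of effects, 469 and 390 for no IL-2 at 4 h and 8 h and 293 at 1 h of IL-2. With a fixed scan-day block, which leaves no value for comparisons across scan years other than the difference of effects, they were 46 for that difference and 262 at 1 h. With a replicate block they were 82 and 288. In fits to only the arrays compared they were 9540 for IL-2 against no IL-2 at 8 h, 74 for the difference, 1287 for no IL-2 4 h, and 27 and 444 at 0.5 and 24 h of IL-2. The difference of effects had 4 calls with a pseudocount of 64, 5 under quantile normalisation, 2 under median centring, 5 without a filter, 57 with the 75th percentile filter, 2 without the variance trend and 61 without scan day 2. Median centring gave 1135 for no IL-2 8 h, and leaving out scan day 2 gave 1594 at 24 h. On scan day 3 alone the counts were 22, 100, 521, 2613, 3877, 2023, 1817 and 3 at 0.5, 1, 2, 4, 8, 10, 12 and 24 h, and 4106 for the F test; the 0.5, 10, 12 and 24 h groups have 1 array on that day, assumed to vary like the other groups. At 2-fold or more they were 2516 for IL-2 against no IL-2 at 4 h, 1409 and 871 for no IL-2 at 4 h and 8 h, and 2690, 3212, 3742, 3954, 3750, 2921 and 1656 from 4 to 24 h of IL-2. At an adjusted p under 0.01 they were 2318 and 3871 for IL-2 against no IL-2 at 4 h and 8 h, 2 for the difference, 822 and 678 for no IL-2 at 4 h and 8 h, and 25, 98, 385, 2765, 3185, 3721, 3889, 3711, 2773 and 1153 from 0.5 to 24 h of IL-2.

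With 1 array left out at a time the counts ran from 2711 to 5887 and 4756 to 5435 for IL-2 against no IL-2 at 4 h and 8 h, 0 to 63 for the difference, 1325 to 2569 and 590 to 1814 for no IL-2 at 4 h and 8 h, and 7930 to 10087 for the F test. For IL-2 against starved 0 h they ran from 19 to 48 at 0.5 h, 83 to 188 at 1 h, 346 to 906 at 2 h, 3671 to 4762 at 4 h, 3667 to 5419 at 6 h, 4274 to 6161 at 8 h, 4402 to 6173 at 10 h, 4075 to 5993 at 12 h, 2751 to 4688 at 16 h and 2133 to 3729 at 24 h. The arrays that move a count beyond 1.5 times are named in the results with each comparison.

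Results that reversed were the cytotoxic list at 4 h of IL-2 against no IL-2, whose test turned upward at a median of −0.0112 under quantile normalisation, and the proteasome in no IL-2 8 h (0.0269 under quantile normalisation, test turned downward). Ribosome biogenesis in the difference of effects reversed with array weights (−0.0511) and without the array labelled no IL-2 4 h replicate 2 (−0.14, the lowest with 1 array left out; highest 0.41), and Ccnd3 with the mean of its probe sets (−0.0418 at 8 h against no IL-2 and −0.0756 at 4 h against starved 0 h). At 0.5 h of IL-2, cholesterol synthesis was at −0.16 without IL-2 0.5 h replicate 3 (highest with 1 array left out 0.15), aminoacyl tRNA synthetases at 0.0755 and glycolysis at 0.30 without scan day 2, and on scan day 3 alone these were 0.0982 and 0.37 and the fibroblast markers 0.12. Both the 0.5 h and the 12 h values on scan day 3 rest on 1 IL-2 array. On that day alone G2/M at 12 h was −0.97 and cholesterol synthesis at 16 h −0.31.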

Other observations

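The comparison of scan years and the genes named in this part were chosen after the data were seen.

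Bnip3, a mitochondrial protein that answers to low oxygen, lay at −1.88 after 4 h and −2.38 after 8 h more without IL-2, beside the falls of Slc2a1 and Hk2. Cd8a, the alpha chain of the CD8 coreceptor, was higher with IL-2 by 1.52 at 4 h and 2.68 at 8 h against no IL-2, whereas Zap70, a kinase of the T cell receptor, lay at −1.03 and −1.27, and the T cell identity list as a whole was not called. Cd28, a costimulatory receptor, lay at −2.51 after 10 h of IL-2.

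The probe sets that separated all arrays of scan year 2 from all of scan year 1 were 126 higher and 84 lower in scan year 2. Mean differences between the years were −5.10 for Cysltr1, 3.98 for Rnf207, −3.35 for Sema3a, −3.33 for Spin4, −3.27 for Myl10, −3.23 for Csn2 and 3.15 for Cd7. Rnf207 in scan year 1 (mean log2 signal 5.61) and Sema3a (5.17), Cysltr1 and Spin4 in scan year 2 lay near background, so the sizes of these differences are not exact. The 100 most abundant probe sets took a median of 12.4% of the summed signal in scan year 2 and 9.43% in scan year 1. Array weights were lowest for IL-2 24 h replicate 2 (0.221), IL-2 24 h replicate 1 (0.229), the array labelled no IL-2 4 h replicate 2 (0.321) and IL-2 16 h replicate 1 (0.344).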
